A study of Homo sapiens with 4 samples.

How the data were processed

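Total RNA of SV80 cells, a human fibroblastoid line transformed by SV40, was profiled on 4 Agilent 2-colour whole-genome oligonucleotide arrays. Per the labels, cells received a lentivirus expressing a caspase-8 siRNA or a control lentivirus, RNA was extracted with a silica column kit, and linearly amplified RNA of the knockdown cells (Cy5) and of the control cells (Cy3) was hybridised together. The dyes were assigned in the same way on all 4 arrays, so dye and treatment coincided and no dye term could be fitted. The labels' design text calls the 4 replicates of each condition biological. Each array carried its own control, so that the log ratio was already paired by array.

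Arrays were scanned and quantified with Agilent Feature Extraction 9.5 per the submitters' processing notes, and with release 9.5.3.1 per the file headers. The scanner files hold, per the file headers, mean pixel intensity and median local background intensity of each spot in green (Cy3) and red (Cy5), on a linear scale and not normalized. They also hold processed intensities that Feature Extraction had background-subtracted, detrended and dye-normalized, and, per the file headers, a log10 ratio of red over green made from these. The deposited value table of the authors holds 1 log10 ratio per spot for each of the 4 arrays. Each of its columns had a median of 0, and 5.68% to 7.70% of the gene spots were listed at exactly 0. No source used here states how the table was scaled, centred or oriented. The places of spike-in spots, corner spots and repeated spots showed that its lines follow the spot numbers and that its scale is log10. These spots did not settle its centring or its direction. The direction was taken as Cy5 over Cy3, as the spike-in spots of the table ran the same way as those of scanner arrays 2 and 3 (Pearson's r over 10 spike-in probes 0.992 and 0.949 against the first column), though not as those of scanner array 4 (0.0754). The corner spots did not bear this out, with a mean log10 ratio of 0.20 to 0.36 in the columns of the table and of -0.69, -0.00605 and -0.0268 on scanner arrays 2, 3 and 4. Of the 3 probes of the siRNA target CASP8, A_24_P157087 and A_24_P148499 read lower in every column of the table (mean log2 ratios -2.34 and -2.03). With the sign turned they would read higher in knockdown cells, so these 2 probes argue for the labelled direction. A_23_P209389, at 0.38, goes the other way.

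The scanner file of array 1 was damaged in the copy used here and none of its values were used. The fit planned for 4 arrays therefore ran on arrays 2, 3 and 4. The deposited table, planned as an alternative, was also analysed in its own right on all 4 arrays, a choice made after the data were examined, because its values did not match those of the scanner files. The design, the alternatives to the scanner analysis, the gene lists and the rule for named genes were otherwise fixed before the data were examined.

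In the scanner files, background was corrected with normexp (offset 50) on all spots, ratios were normalized by loess within each array with control spots at weight 0, and control spots and outlier spots (78 to 112 per array) were then removed. Of 41000 probes, 35695 were well above background in at least 1 channel on 3 arrays and were kept. Spots of one probe were averaged, and of several probes of a gene the one with the highest mean log2 intensity stood for the gene. Several kept probes disagreed in sign for 41.5% of 6797 genes in the scanner files and for 46.8% of 7218 genes in the value table. In the value table, log10 ratios were turned into log2, exact zeros were taken as missing, and 37783 probes with at least 3 values were kept. Since the table holds no intensities, the brightest probe was taken from the scanner files. Gene names came from the array's own annotation. They were updated through the RefSeq accessions of a GRCh38.p14 gene table, used for names only, which matched 23680 probes; another 2073 probes took the name of a probe with the same older name. Coordinates are those of the array annotation on hg18.

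Log2 ratios were tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, 2-sided, with Benjamini-Hochberg adjustment over all genes of a source and a threshold of 0.05. Gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 and adjusted over the 35 lists. An estimated correlation and fry were alternatives. Each list's median was also placed among 10000 random lists of equal size matched on intensity in 20 bins. For both sources these were the intensities of the scanner files. The 35 lists covered the death receptor complex, the BCL2 family, necroptosis and pyroptosis, interferon-stimulated genes, RNA sensing, NF-kB targets, the interleukin-1 system, class I antigen presentation, S phase, mitosis and p53 targets. They also covered collagens and matrix, matrix proteases, adhesion, TGF-beta targets, immediate early genes, the unfolded protein response, heat shock, oxidative stress, hypoxia and glycolysis, sterol synthesis, ribosomal proteins, oxidative phosphorylation and histones. Wnt and Notch, growth factors, autophagy and lysosome, RNAi machinery, genes near CASP8, and markers of epithelial, endothelial, leukocyte, neural, muscle, and adipocyte and hepatocyte cells completed them.

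The named genes were every CASP8 probe, the 12 largest rises and the 12 largest falls among changed genes with the same sign on all arrays and a proper gene symbol, and members of each list. Where no gene had changed, the 12 genes with the smallest p in each direction took their place. Of a list past the camera threshold, up to 4 changed members with the largest ratios were named, and otherwise up to 2 members with the largest ratios, changed or not. Some genes that this rule takes are not reported here.

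Alternatives to the scanner analysis were no background subtraction, normexp with offset 10, the log ratio of Feature Extraction, median centring, loess with scaling between arrays, the value table, no filter on dim probes, probes above background in both channels on all arrays used, the mean of a gene's probes, separate channels (lmscFit), eBayes with trend and robust settings, a minimum fold of 1.2 (treat), and each array left out. Alternatives to the value table analysis were chosen after the data were examined. The analysis was tested on simulated data with known changes. Few genes were changed in these data, and noise was drawn independently for each gene at its observed SD. In the real scanner files 24.5% of genes had an unadjusted limma p under 0.05. The simulated shares therefore do not give the power of the real analysis, nor its false calls among correlated genes. With 3 arrays as in the scanner files (26609 genes), 37 of 66 genes changed 4-fold were called, 0 of 67 changed 2-fold and 1 of 67 changed 1.5-fold, with 0 of 26409 unchanged genes. With 4 arrays as in the value table (27520 genes), 64 of 66 genes changed 4-fold were called, 53 of 67 changed 2-fold and 24 of 67 changed 1.5-fold, with 10 of 27320 unchanged genes. The number of arrays limits the precision of all values, and the 3 scanner arrays lay on 1 slide, so that no slide effect could be tested.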

Results

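Gene expression in SV80 fibroblastoid cells carrying a caspase-8 siRNA lentivirus was compared with that in cells carrying a control lentivirus, to learn how loss of caspase-8 affects the transcriptome. Each of 4 arrays held knockdown RNA in Cy5 and control RNA in Cy3. Scanner values of arrays 2, 3 and 4 were used, and the deposited table of log ratios covered arrays 1 to 4. On the scanner arrays, 81.8% to 88.2% of 43376 gene spots were well above background in Cy3 and 89.8% to 96.0% in Cy5, with 0 saturated spots. Log2 ratios are knockdown over control, given with the moderated standard error (SE) of limma unless an SD is named. This SE draws each gene's variance toward that of all genes, so it differs from the plain SE of the n arrays. For the value table this direction was taken from the labels' dyes and the spike-in spots and is not stated with the table. Every rise and fall given from it would change places if the table ran the other way. The siRNA target CASP8 read lower there at 2 of its 3 probes, which argues for the labelled direction, and higher at its brightest probe. As the dyes were never swapped, a gene's dye preference could not be separated from the effect of knockdown.

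CASP8, the initiator caspase of death receptors and the target of the siRNA, gave different answers at its 3 probes, which lie in the gene on chromosome 2 (hg18). Probe A_24_P157087 (201860083 to 201860142) read lower in the knockdown channel on all arrays, at -1.79 ± 0.59 (SD, n = 3) in the scanner files and -2.34 ± 0.29 (SD, n = 4) in the value table, which leaves 28.9% and 19.8% of the control level. Probe A_24_P148499 (201844501 to 201844560) read lower too, at -1.02 ± 0.03 (SD, n = 3) and -2.03 ± 1.02 (SD, n = 4). Probe A_23_P209389 (201859729 to 201859788), the brightest and the one that stood for the gene, read higher, at 0.55 ± 0.73 (SD, n = 3) and 0.38 ± 0.10 (SD, n = 4). The array annotation assigns the first and the last of these to transcript variant B and A_24_P148499 to variant E, and all 3 were well above background in both channels on the 3 scanner arrays.

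On single arrays, A_24_P157087 gave -1.48, -1.43 and -2.47 on scanner arrays 2, 3 and 4, and -2.72, -2.02, -2.33 and -2.28 in the table. A_23_P209389 gave -0.16, 1.31 and 0.49 on the scanner arrays, and 0.39, 0.27, 0.36 and 0.52 in the table. In limma fits over probes, the scanner values of A_24_P157087 and A_24_P148499 missed the threshold (adjusted p = 0.0531 and 0.0527), while in the table both fell (adjusted p = 0.00586 and 0.0345). At the level of genes, the brightest probe gave an adjusted p of 0.315 in the scanner files and rose in the table (adjusted p = 0.0311), and the mean of the 3 probes was -0.76 and -1.33. The sequence that the siRNA targets is not given in the sources used here, and the specificity of the brightest probe for CASP8 was not tested, so that what its gene-level value measures is not settled. The target therefore checks the labelled direction at 2 of its 3 probes.

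**Figure D1:**
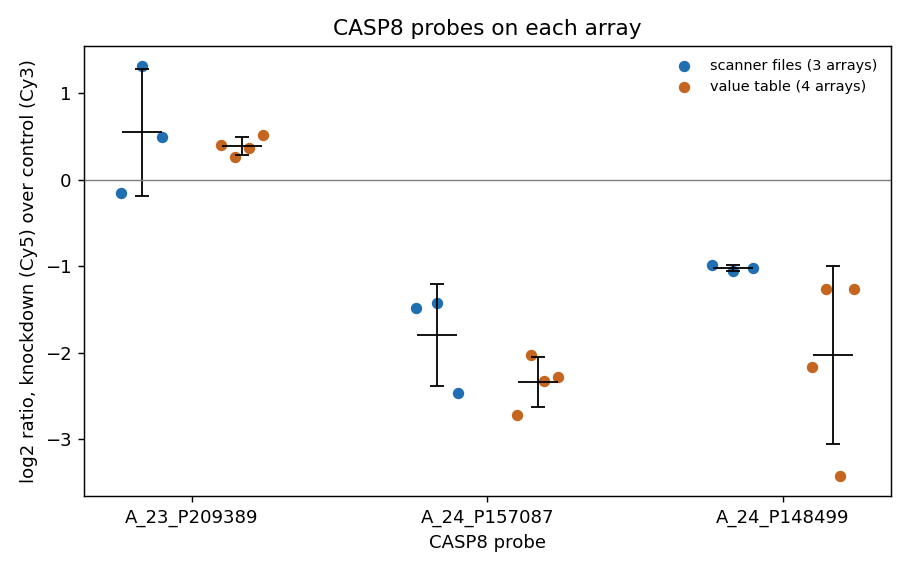
Log2 ratio (knockdown over control) of the 3 CASP8 probes on each array, in the scanner files and in the deposited value table, with the mean and SD. A_24_P157087 and A_24_P148499 lie below 0 on every array of both sources, whereas A_23_P209389 lies above 0 on all but 1 array.

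In the scanner files, interferon-induced transcripts were among the genes with the strongest evidence, although no single gene passed the threshold. IFI27, an interferon-inducible mitochondrial protein, stood at 4.01 ± 0.40 (SE, n = 3), a 16.2-fold higher signal, at a probe on chromosome 14 (93652682 to 93652741). BST2 (tetherin), which holds budding virions at the cell surface, stood at 2.03 ± 0.12, and GBP5, an interferon-inducible GTPase, at 1.37 ± 0.14. IL13RA2, the decoy receptor of interleukin-13, stood at 2.09 ± 0.13. PMAIP1 (NOXA), a BH3-only protein that promotes apoptosis, stood at 1.32 ± 0.13, and the ETS transcription factor FLI1 at 1.15 ± 0.11.

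The other genes with the smallest p on the higher side were BCAS4 (1.95), MPP4 (1.70), the protease inhibitor TFPI2 (1.66), the BMP antagonist GREM1 (1.41), ARAP2 (1.34) and the decay kinase SMG1 (1.34). On the lower side were serine dehydratase SDS at -2.27 ± 0.16 (SE, n = 3), the kinesin KIFC3 at -1.57 ± 0.13, the Ran GTPase activator RANGAP1 at -1.54 ± 0.13 and the actin crosslinker FLNC at -1.47 ± 0.12. PPP5C (-1.47), ZNF768 (-1.43), the decapping scaffold EDC4 (-1.34), the kinase MAPK12 (-1.31), RAB40C (-1.28), HDGFL2 (-1.26), ADAM15 (-1.23) and DBNL (-1.21) completed this group. All of these genes had a limma adjusted p of 0.0653 and the same sign on 3 of 3 arrays.

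With limma, 0 of 26615 genes passed an adjusted p of 0.05 in the scanner files, while 6516 (24.5%) had an unadjusted p under 0.05, 3040 of them higher and 3476 lower. The count differed between processing settings of the same 3 arrays. It was 1428 with normexp offset 10, 2064 with the log ratio of Feature Extraction, 609 with median centring, 1316 with scaling between arrays, 2281 with trend and robust settings and 2680 with separate channels. The value table, which differs in source, in the number of arrays and in the genes tested, gave 3107. There IFI27 fell by 0.45 (limma adjusted p = 0.0405), and BST2 (-0.22), IL13RA2 (-0.26), FLI1 (-0.51), TFPI2 (-0.10), GBP5 (-0.05), PMAIP1 (-0.05), KIFC3 (0.10), ZNF768 (0.10) and EDC4 (0.17) also had the opposite sign.

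**Figure D2:**
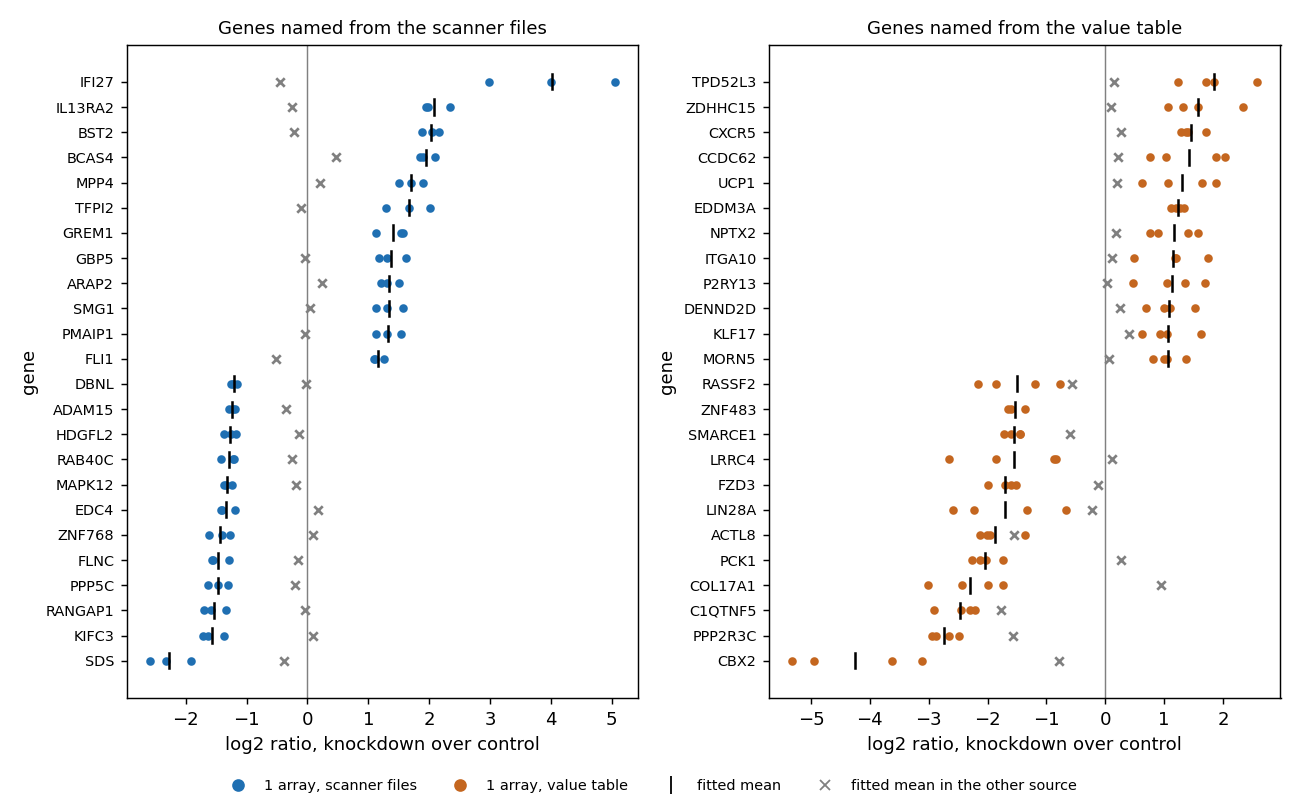
Log2 ratio (knockdown over control) of the genes named by size or p, with 1 point per array, a bar for the fitted mean and a cross for the fitted mean in the other source. The scanner genes missed the threshold at a limma adjusted p of 0.0653. With the table in its assumed direction, 7 of those higher and 3 of those lower have the opposite sign there. EDDM3A and ZNF483 are drawn although their probes were not well above background in Cy3 on any scanner array.

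Interferon-stimulated genes stood higher as a group in the scanner files. Of 44 measured members, 34 were higher and 10 lower, with a median of 0.59, above 100% of lists matched on intensity, and 0 passed over all genes tested. Adjusted over the list alone, 21 rose and 2 fell. IFI27 (4.01) and IFI6 (2.38) had the largest ratios. The camera adjusted p was 3.6e-05, and the adjusted p was 0.71 with an estimated correlation.

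Class I antigen presentation moved the same way, with 15 of 21 members higher and a median of 0.35. Adjusted over the list alone, 9 rose and 1 fell. The light chain B2M stood at 1.78 ± 0.25 (SE, n = 3, adjusted p = 0.0656) and HLA-C at 1.06 ± 0.15 (SE, n = 3, adjusted p = 0.0656). The camera adjusted p was 0.0303, against an adjusted p of 0.976 with an estimated correlation, and the call ended with normexp offset 10 (adjusted p = 0.0872), with the log ratio of Feature Extraction (0.18), with the mean of probes (0.13), with trend and robust settings (0.131) and without array 2 (0.275).

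Genes of S phase and of sterol synthesis stood lower as groups in the scanner files. Of 35 S phase members, 27 were lower, with a median of -0.35, and adjusted over the list alone 8 fell and 0 rose. The helicase subunit MCM7 stood at -1.06 ± 0.22 and the replication factor GINS1 at -1.05 ± 0.16 (SE, n = 3). Of 31 sterol synthesis members, 23 were lower, with a median of -0.34, and adjusted over the list alone 13 fell and 2 rose. The mevalonate pathway enzyme MVD stood at -1.03 ± 0.11. Each list had a camera adjusted p of 0.000535, with an adjusted p of 0.71 for S phase and 0.966 for sterol synthesis with an estimated correlation.

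The cell death lists did not shift as groups in the scanner files. The medians were 0.02 for 28 members of the death receptor complex, 0.04 for 21 of the BCL2 family and 0.04 for 15 of necroptosis and pyroptosis, with camera adjusted p of 0.971, 0.736 and 0.892. Among their members, FAS stood at 1.01 ± 0.15, the inhibitor of apoptosis BIRC3 at 1.08 ± 0.15 and the inflammatory caspase CASP4 at 1.32 ± 0.16 (SE, n = 3). NLRP3 stood at 1.01 ± 0.22 and the BH3-only gene BBC3 (PUMA) at -2.05 ± 0.52. BBC3 moved to -1.35 without array 2, to -2.74 without array 4 and to -0.73 with the mean of its probes. Of 21 RNA sensing genes, with a median of 0.07 and a camera adjusted p of 0.971, RIGI stood at 1.44 ± 0.19 and IRF7 at -0.91 ± 0.24. None of these genes passed the limma threshold.

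In the deposited value table, the largest falls were in CBX2, a polycomb subunit, at -4.25 ± 0.39 (SE, n = 4, 19.0-fold, chromosome 17, 75370520 to 75370579), and PPP2R3C, a phosphatase subunit, at -2.74 ± 0.10. C1QTNF5 fell by 2.47 ± 0.13, COL17A1, the transmembrane collagen of hemidesmosomes, fell by 2.29 ± 0.21, and PCK1, an enzyme of gluconeogenesis, fell by 2.04 ± 0.10. ACTL8 (-1.87), the let-7 regulator LIN28A (-1.71), the Wnt receptor FZD3 (-1.70), LRRC4 (-1.55), the chromatin remodeller subunit SMARCE1 (-1.55) and RASSF2 (-1.50) also fell. The largest rises were TPD52L3 at 1.84 ± 0.21, the palmitoyltransferase ZDHHC15 at 1.58 ± 0.21, the chemokine receptor CXCR5 at 1.45 ± 0.09 and CCDC62 at 1.43 ± 0.24 (SE, n = 4). UCP1 (1.30), NPTX2 (1.16), the integrin chain ITGA10 (1.16), the nucleotide receptor P2RY13 (1.14), DENND2D (1.08), KLF17 (1.06) and MORN5 (1.06) rose as well. Of the 12 largest rises 6, and of the 12 largest falls 11, lay on probes well above background in both channels on all 3 scanner arrays. The Cy3 channel was well above background on only 1 scanner array for TPD52L3, ZDHHC15 and P2RY13 and on 2 for UCP1 and MORN5, so that the size and rank of these rises are uncertain. The table holds no intensities and did not match these scans, so the detection behind its own values is not known for any gene. EDDM3A and ZNF483 were also among the largest changes by the rule, but no size is given for them, as their probes were not well above background in Cy3 on any of the 3 scanner arrays, nor in Cy5 on any for EDDM3A and on more than 1 for ZNF483.

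In the scanner files COL17A1 (0.94 ± 0.14, SE, n = 3, limma adjusted p = 0.0672), PCK1 (0.26) and LRRC4 (0.11) had the opposite sign, and CBX2 stood at -0.78 ± 0.15, none of them past the threshold. In all, limma called 3107 of 28142 genes changed in the table, 1611 higher and 1496 lower (1496 higher and 1611 lower with the sign turned), of which 144 rose and 81 fell over 2-fold. The smallest adjusted p was 0.00295, and 8998 genes had an unadjusted p under 0.05. Most calls ended when a single array was left out, with 41 genes called without array 1, 76 without array 3, 56 without array 4 and 1756 without array 2, and a minimum fold of 1.2 left 129.

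Sterol synthesis genes were lower as a group in the table too. Of 32 members, 28 were lower, with a median of -0.20; 8 fell and 0 rose over all genes tested, and 13 fell and 0 rose adjusted over the list alone. The sterol methyl oxidase MSMO1 fell by 0.49 ± 0.08 and INSIG1, which retains the sterol sensor in the endoplasmic reticulum, fell by 0.48 ± 0.07 on the log2 scale (SE, n = 4). MSMO1 turned to 0.21 with the mean of its probes. The camera adjusted p was 6.46e-06, and the adjusted p was 0.768 with an estimated correlation.

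S phase genes were lower as a group, with 24 of 35 members lower and a median of -0.16 at percentile 0.07 of lists matched on intensity; 7 fell and 0 rose over all genes tested, and 8 fell and 0 rose adjusted over the list alone. RRM1, the large subunit of ribonucleotide reductase, fell by 0.62 ± 0.07, MCM7 by 0.55 ± 0.09, cyclin CCNE2 by 0.55 ± 0.09 and the licensing factor CDT1 by 0.51 ± 0.08 (SE, n = 4). Of 35 genes of hypoxia and glycolysis, 24 were lower, with a median of -0.08 at percentile 5.36 of lists matched on intensity, and 7 fell and 0 rose both over all genes and adjusted over the list alone. Among them ENO2 fell by 0.49 ± 0.07, BNIP3L by 0.48 ± 0.10, NDRG1 by 0.46 ± 0.07 and hexokinase HK2 by 0.41 ± 0.07 (SE, n = 4). The camera adjusted p was 0.00699 for S phase and 0.00948 for hypoxia and glycolysis, and the adjusted p was 0.768 for each with an estimated correlation. Both calls ended after loess on the scanner intensity (adjusted p = 0.0577 each), and that of hypoxia and glycolysis ended without array 1 (0.0959). In the scanner files ENO2 was lower too (-0.38), but BNIP3L (0.39), NDRG1 (0.40) and HK2 (0.18) had the opposite sign, none of them past the threshold.

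**Figure D3:**
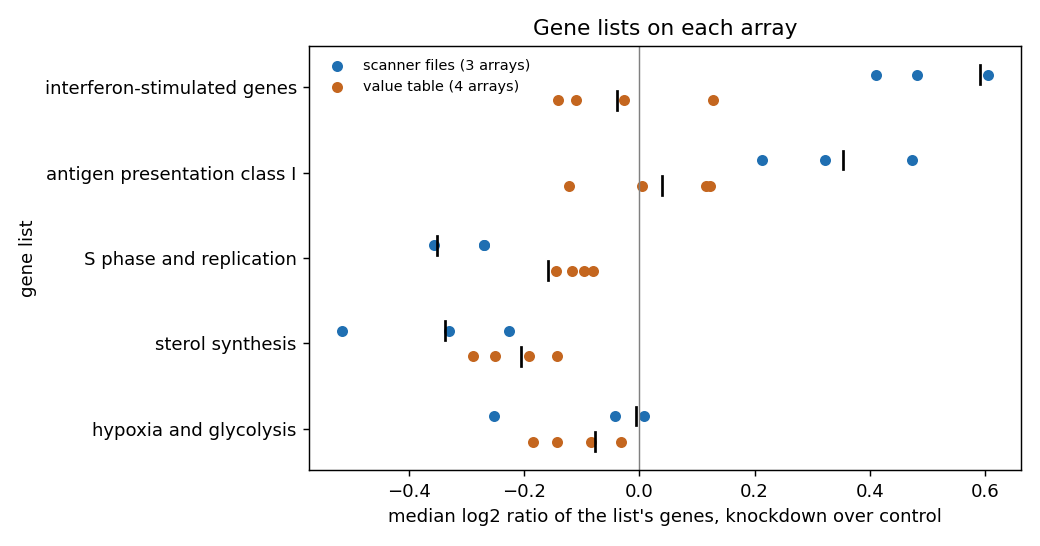
Median log2 ratio (knockdown over control) of the 5 gene lists past the camera threshold in either source, with 1 point per array for its median over the list and a bar for the median of the fitted ratios. Sterol synthesis (-0.34 and -0.20) and S phase (-0.35 and -0.16) lie below 0 in both, and interferon-stimulated genes lie at 0.59 in the scanner files and at -0.04 in the table.

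Interferon-stimulated genes had a median of -0.04 in the table, where 1 of 43 rose and 5 fell, with the same counts adjusted over the list alone and a camera adjusted p of 0.343. Class I antigen presentation had a median of 0.04, with 2 of 21 members up and 1 down (camera adjusted p = 0.898). In the death receptor complex, the adaptor FADD fell by 0.39 ± 0.06 and TNFAIP3 (A20) rose by 0.33 ± 0.06 (SE, n = 4), with 1 of 28 members up and 2 down. The BCL2 family list also holds APAF1, CASP9 and CYCS, which are not BCL2 proteins. In this list APAF1 fell by 0.58 ± 0.07 and BBC3 rose by 0.52 ± 0.10, with 2 of 21 up and 3 down. The pore-forming gasdermin GSDMD fell by 0.36 ± 0.07 while CARD8, at -0.35 ± 0.08, missed the threshold (adjusted p = 0.0531), with 0 of 14 up and 2 down. Of 22 RNA sensing genes 0 rose and 2 fell, among them IRF7, which fell by 0.82 ± 0.16. The camera adjusted p of these 4 lists was 0.0841, 0.566, 0.14 and 0.125. With fry, which tests whether a list moves on balance one way and does not compare it with other genes, the death receptor complex (21 of 28 lower, median -0.07) and necroptosis and pyroptosis (9 of 14 lower, median -0.14) passed as lower, each with an adjusted p of 0.0463. The adjusted p was 0.768 for both with camera at an estimated correlation.

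The scanner files and the value table, which should describe the same arrays, differed. Across 25734 genes tested in both, Pearson's r of the log2 ratios was 0.12 and Spearman's rho 0.14, over genes, which are not independent replicates. Of 2916 genes called in the table and tested in both, 1793 (61.5%) had the same sign in the scanner files, and 54.9% of all genes did. With the sign of the table turned, Pearson's r would be -0.12 and Spearman's rho -0.14, and these shares 38.5% and 45.1%. The interferon-stimulated genes differed between the sources (camera adjusted p = 2.24e-06), with an adjusted p of 0.848 with an estimated correlation. Over spots, arrays correlated at 0.42 to 0.49 within the scanner files, at 0.26 to 0.52 within the table and at -0.05 to 0.28 between them.

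**Figure D4:**
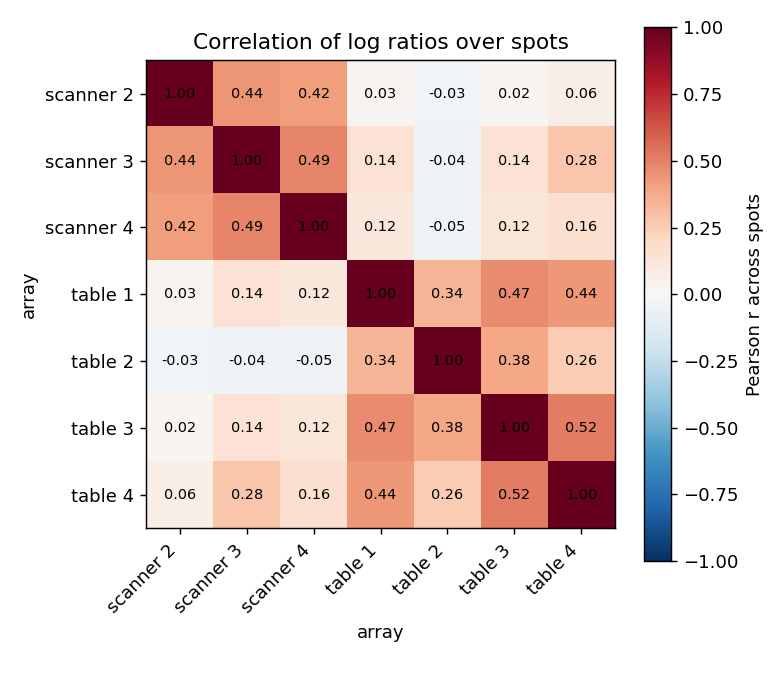
Pearson correlation over spots between the log ratios of the 3 scanner arrays and the 4 columns of the value table. Arrays correlate within a source (0.42 to 0.49 and 0.26 to 0.52), and the 12 pairs across sources lie between -0.05 and 0.28.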

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

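All 3 tests of the mismatch between the sources, and the test of interferon-stimulated genes on single arrays, were chosen after the result was seen. In 52 results of the value table with 4 values each, 0 had an array far from the others. Most were genes named because they were called, many of them also for having the same sign on all arrays. This selection favours arrays that lie together, so the count could not show whether an array stands apart.

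The value table and the scanner files disagreed over the same 3 arrays. If the table's lines belonged to other spots, repeated spots of a probe would scatter like different probes, but their SD was at most 0.106 of that of all spots. If columns had been given to the wrong samples, some pair should correlate highly, but the highest of the 12 correlations was 0.278. If the table were another processing of the same scans, the uncorrected ratio should follow its own column, but the highest such correlation was 0.166. Whether the table comes from other hybridisations stays open, and no biological explanation was tested.

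Interferon-stimulated genes stood higher in the scanner files and not in the table. The scanner call had a camera adjusted p of 3.6e-05, but an adjusted p of 0.71 with an estimated correlation. An intensity trend is argued against by a median at the 100th percentile of lists matched on intensity, and a single array by a lowest array median of 0.41. The difference between the sources itself, with their arrays taken as unpaired, had a camera adjusted p of 2.24e-06 and an adjusted p of 0.848 with an estimated correlation. Cells of both channels received a lentivirus, so a response to lentivirus that they share cancels in the ratio. Caspase-8 knockdown, a response to the siRNA or to a difference between the viruses, and the dyes stay open as untested explanations. A dye preference of these genes would be expected in the table too, where the list's median was -0.04. Whether the table comes from the same hybridisations is open, so this does not settle the matter.

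Sterol synthesis genes stood lower in both sources by camera, with an adjusted p of 0.966 in the scanner files and 0.768 in the table with an estimated correlation. In the scanner files an intensity trend is argued against by a median at percentile 0.37 of lists matched on intensity. The percentile was lower still in the table, but the matching there also used scanner intensities. It therefore cannot decide on a trend with the table's own intensities. A single array is argued against by medians of at most -0.14 on every array of both sources. The difference between the sources was not past the threshold (camera adjusted p = 0.483), which does not show that they were alike. That test took the arrays of the sources as unpaired and the table in its assumed direction. A dye preference of these genes and caspase-8 knockdown stay open as untested, and as the direction of the table is not stated, the list would be higher there with the sign turned.

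The numbers of calls were set against those after turning the sign of arrays, which gives too few splits for a share under 0.05. In the scanner files the real split gave 6516 genes at an unadjusted p under 0.05. The highest other number was 435, so that of 4 splits only the real split gave as many. In the table the real split gave 3107 called genes, with 8998 genes at an unadjusted p under 0.05. The highest other number of called genes was 0, so that of 8 splits only the real split gave as many.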

How the results depend on the processing

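All alternatives to the value table analysis, and the single CASP8 probes, were chosen after seeing the data, and where a value moved the cause was not tested. With limma, genes called in the scanner files went from 0 (6516 at an unadjusted p under 0.05) to 1428 with normexp offset 10 (538 higher, 890 lower), 2064 with the log ratio of Feature Extraction (913 and 1151), 609 with median centring (216 and 393), 1316 with scaling between arrays (400 and 916), 2281 with trend and robust settings (956 and 1325), and 2680 with separate channels (1068 and 1612). The value table, another source with 4 arrays and other genes tested, gave 3107. The count stayed at 0 with no background subtraction, no filter on dim probes, both channels on all arrays, the mean of probes, a minimum fold of 1.2 and each of the 3 arrays left out. The 4 shifted lists became 0 with an estimated correlation, 1 with fry (interferon-stimulated genes) and 4 to 7 with an array left out. The log2 ratio of CASP8 at the brightest probe was 0.55 and turned to -0.76 with the mean of probes, -1.79 at A_24_P157087 and -1.02 at A_24_P148499, was 0.38 and past the threshold in the value table, and ranged from 0.17 to 0.90 with an array left out.

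In the value table, the 3107 called genes became 129 with a minimum fold of 1.2 and 41 to 1756 with an array left out. Of the calls without array 1, 2, 3 and 4, 39 of 41, 1483 of 1756, 75 of 76 and 55 of 56 were shared with those of all arrays, and fewer arrays by themselves lower the number. The count was 3034 with zeros kept, 4015 on bright probes, 2599 with the mean of probes, 4209 with trend and robust settings and 2911 after loess on scanner intensity. The 3 shifted lists became 1 after loess on scanner intensity, 0 with an estimated correlation, 6 with fry and 2 to 7 with an array left out. CASP8, at 0.38, turned to -1.33 with the mean of probes, -2.34 at A_24_P157087 and -2.03 at A_24_P148499. It was 0.34 to 0.42 with an array left out, where it missed the threshold without array 1, 3 or 4 (limma adjusted p = 0.115, 0.127 and 0.0917).

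Taking the value table, in its assumed direction, in place of the scanner files turned the sign of 13 named genes. They went to -0.22 for BST2, -0.26 for IL13RA2, -0.51 for FLI1, -0.45 for IFI27, -0.0453 for GBP5, -0.0461 for PMAIP1 and -0.10 for TFPI2. Values were 0.10 for KIFC3, 0.10 for ZNF768, 0.17 for EDC4, -0.13 for FAS, 0.52 for BBC3 and -0.0226 for HLA-C. The interferon-stimulated list turned to -0.0396. With the sign of the table turned, these would keep their sign and the other named scanner genes measured in both sources would reverse. MSMO1 in the table turned to 0.21 with the mean of probes. Of all other values of named genes under alternatives, 310 kept sign and side of the threshold in the scanner files and 208 passed it anew; in the value table, both were kept by 258, while 127 missed the threshold and 2 passed it anew. No scaling moved the median of all genes by more than 0.08. Each array carried both conditions, so the analysis was already paired by array.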

Other observations

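The test of dim probes was planned before its result was seen, and the shared genes were picked out after seeing the data. Some genes moved alike in both sources. Among genes tested in both, 312 were called lower in the table and had a lower ratio with an unadjusted p under 0.05 in the scanner files, against 192 for independent lists, and 295 were higher in both, against 174. Opposite signs were found for 106 and 121 genes, against 166 and 201. C1QTNF5 (-1.77 in the scanner files, -2.47 in the table), PPP2R3C (-1.56 and -2.74) and ACTL8 (-1.55 and -1.87) were among the shared falls. The unnamed probe A_32_P167111 had -3.74 and -6.05. A dye preference of these genes was not tested, and as the direction of the table is not stated, the shared and the opposite counts would change places with its sign turned.

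Lists not yet described passed camera in neither source, and their medians in the scanner files and in the table follow. Ribosomal proteins (0.25 and 0.01) and oxidative phosphorylation (0.29 and -0.04) lay at percentiles 99.7 and 99.96 of matched lists in the scanner files, with camera adjusted p of 0.138 and 0.24. TGF-beta targets were at -0.24 and -0.02, collagens and matrix at -0.12 and -0.11, and immediate early genes at -0.17 and -0.03. Genes near CASP8 were at 0.22 and -0.07 (camera adjusted p = 0.0793 and 0.52). Their difference between the sources, with arrays taken as unpaired, had an adjusted p of 0.0452 with camera and 0.848 with an estimated correlation.

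Of the signalling and stress lists, NF-kB targets were at 0.08 and 0.08, the interleukin-1 system at 0.12 and 0.01, p53 targets at 0.05 and -0.03, and mitosis at 0.04 and -0.07. The unfolded protein response was at 0.00254 and -0.05, heat shock at -0.00279 and -0.05, oxidative stress at 0.18 and 0.03, autophagy and lysosome at 0.03 and 0.01, and RNAi machinery at -0.08 and -0.06. Matrix proteases were at 0.11 and 0.05, adhesion at 0.02 and 0.03, Wnt and Notch at 0.08 and 0.09, growth factors at 0.02 and -0.02, and histones at -0.14 and 0.13. Hypoxia and glycolysis, shifted in the table, was at -0.01 in the scanner files (camera adjusted p = 0.862). The sign of the median, the mean and the test differed in the scanner files for the death receptor complex, the BCL2 family, RNA sensing, the interleukin-1 system, mitosis, p53 targets, adhesion, the unfolded protein response, heat shock, hypoxia and glycolysis, autophagy and lysosome, neural markers and muscle markers. It differed in the table for NF-kB targets, the interleukin-1 system, p53 targets, oxidative stress and autophagy and lysosome.

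Markers of other cell types had medians of -0.06 and -0.04 for epithelial, -0.01 and 0.05 for endothelial, 0.05 and 0.13 for leukocyte, 0.05 and 0.16 for neural, 0.08 and 0.04 for muscle, and 0.14 and -0.01 for adipocyte and hepatocyte cells. With fry, which does not compare a list with other genes, leukocyte markers (adjusted p = 0.0472) and neural markers (adjusted p = 0.0463) passed as higher in the table, with camera adjusted p of 0.0841 and 0.331, and an adjusted p of 0.768 for each with camera at an estimated correlation. The other lists past fry in the table, all lower with an adjusted p of 0.0463, were the death receptor complex, necroptosis and pyroptosis, S phase and sterol synthesis.

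A bias of the ratio at low intensity was tested for the genes called higher in the table. Intensities were those of the scanner files, as the table holds none, so a bias with the table's own intensities could not be tested. Their share was 5.08% in the dimmest 5629 genes and 4.33% in the brightest 5629, a ratio of 1.17, with 6.25%, 7.36% and 5.60% in the groups between them, so that it did not climb steadily toward dim probes. The share called lower was 2.93% in the dimmest genes and 6.61% in the brightest, and their median log2 ratios were 0.06 and -0.01. Falls were thus called more often among bright genes. With the sign of the table turned, 2.93% and 6.61% would be the shares called higher. Removing an intensity trend changed the number of calls from 1611 to 1424, so that the test decided neither way.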
